A study of Mus musculus with 2 samples.

How the data were processed

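ATAC-seq libraries were made from whole intestine of mouse embryos at day 14.5, in 2 biological replicates, pools of 17 and 34 embryos per the labels. Each replicate was a single library, and the 2 replicates form 1 group. The labels give the mm10 assembly for every peak list. The deposited lists were of 3 kinds per replicate, namely ranked peaks, peaks past a threshold on the irreproducible discovery rate (IDR), and less strict overlap-based peaks. The list descriptions deposited with the samples trace the replicate lists to the alignment of that replicate, and the series lists, which include a conservative thresholded list, to the alignments of both. For the filtered lists they name 1 further input file without its role. The aligner, the peak caller, their versions and parameters are not given in the sources used here. The deposited signal value of each summit is the authors' enrichment measure, and how it was scaled is not given in the sources used here. The authors also give a −log10 p per summit (neg_log10_p), with no adjustment for multiple tests. In both units the values were used only as ranks within a list. The ranked lists also hold the −log10 of the global IDR, and every summit of the thresholded replicate lists lay at or above 1.3 on that scale, an IDR of 0.05.

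The coordinates were checked against the GRCm38 p6 sequence of mm10, and every peak ended within its chromosome. Genes, transcripts and starts came from GENCODE M21, with 21911 protein-coding genes and 132629 starts of annotated transcripts. A peak list can hold several summits in 1 interval. A region was therefore defined as a unique interval with its strongest summit by signal value, a definition not spelled out in the plan fixed before the data were examined. A region was called promoter when that summit lay within 1000 bp of any annotated start and distal otherwise. A gene's promoter counted as open when any summit of the list lay within 1000 bp of 1 of its starts. All other choices of lists, motifs, tests and named genes were fixed before the data were examined, except where stated here. Coordinates are 1-based.

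Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and sequence searches used BLAST 2.17.0. Regions were shared when they overlapped by at least 50% of the shorter region. Overlap and promoter share were compared with 1000 circular shifts along each chromosome, leaving out its first 3 Mb, in one-sided permutation tests. Random positions for region classes numbered 300000. Each of 23 gene lists was compared with 10000 random lists of protein-coding genes of the same size. For open promoters these were matched on the decile of the observed over expected CpG ratio within 500 bp of a start, taking the highest ratio over a gene's starts. For distal regions, counted at the nearest protein-coding start, they were matched on the decile of the length of the gene's territory. Both permutation tests were two-sided with Benjamini-Hochberg adjustment over the 23 lists, and a list was called when the adjusted p was at most 0.05 in both replicates and in the pooled list. All 527 entries of the lists matched a gene of the annotation.

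The gene lists covered intestinal epithelial transcription factors, epithelial structure, absorptive enterocytes, secretory and enteroendocrine cells, stem cells and Wnt response, gut mesenchyme, the Hedgehog pathway, smooth muscle and interstitial cells of Cajal, enteric neurons and glia, endothelium, blood and immune cells, mesothelium, proliferation, housekeeping and Hox genes, and 8 contrast lists of other tissues. Some genes are in more than 1 list, and Sox9 counts under both epithelial transcription factors and stem cells. Named genes were 37 fixed genes, the 3 members of each list with most distal regions in the pooled list, the first 2 members by name without a promoter region in either replicate, the 10 regions ranked highest in both replicates with their nearest gene, and the Hox genes as clusters. Of those that the rule allows, some are not printed. Open Hox promoters are listed as members of their clusters.

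For 38 consensus motifs, 3 of them scrambled controls, the windows of 100 bp on each side of distal summits were compared with windows centred 1000 bp upstream and downstream. The test was an exact two-sided binomial test of discordant windows, and the larger p of the 2 flanks was kept and adjusted over 38 motifs. A motif was called with an adjusted p of at most 0.05 and a ratio of at least 1.2, or at most its inverse, in both replicates and the pooled list. A count of 0 in the flanks was set to 3 windows over both flanks. This floor was chosen after the first motif results were seen. The ratio had first been left undefined, which gave 11 motifs and not 12, with NRF1 as the difference. Choices in the text that leave the plan are the region definition, the use of all summits for open promoters, the larger p of the flanks, the CpG ratio over starts and this floor.

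The tests were checked on simulated data. In 230 lists with nothing planted there were 0 false calls for promoters and 0 for distal regions. Values there were permuted within the same deciles that the random lists were matched on, so few false calls were built in. Errors from neighbouring genes or from spread within a decile could not show. Planted 2-fold and 3-fold excesses of distal regions were recovered in 27.5% and 52.5% of 40 lists, and planted promoter excesses in 80.0%. These shares are for the pooled list alone, whereas a call also needed both replicates. Planted promoter excesses were capped where all members of a list were open, so lists with many open promoters got less than the stated fold. No deficits were planted. A motif planted in 29.3% of distal windows gave an excess of 28.8% and no calls among the other 37 motifs. Summit and flank windows there were all shuffles of the same summit sequences. Real differences between summits and flanks were therefore not part of that check.

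Alternatives planned before the data were examined were the less strict lists, the top-ranked 50% of regions, the conservative pooled list, each replicate alone, other definitions of overlap, lists of equal or own length, promoter windows of 500 and 2000 bp, protein-coding starts, autosomes, unmatched random lists, distal regions within 50 kb, motif windows of 50 and 200 bp and a dinucleotide-shuffled background. Alternatives added after seeing the data were ranks by −log10 p, every summit counted, random lists matched also on an open promoter, and no call for motifs without a flanking match. Mitochondrial matches were BLAST matches to the mitochondrial genome of at least 100 bp at 90% identity. Nuclear copies were matches elsewhere of at least 95% identity over 50% of a region.

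The read alignments, signal tracks and the binary copies of the lists were not used here. The depth per sample is therefore unknown, no coverage was compared, and intervals are 95% Wilson intervals over regions. With 2 libraries in 1 group, tests between samples, pairings and regroupings of samples do not apply. The less strict and the ranked lists served for alternatives and checks, and summits on unplaced scaffolds in the ranked lists were left out of the comparisons.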

Results

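Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in whole mouse intestine at embryonic day 14.5. The series holds 1 tissue at 1 stage in 2 biological replicates. Replicate 1 was a pool of 17 embryos and replicate 2 a pool of 34 embryos, each of both sexes. No read counts were used here, so the depth of each library is unknown. The thresholded peak list of replicate 1 held 35161 summits in 13620 regions, and that of replicate 2 held 42787 summits in 15422 regions (mean 14521 ± 1274 regions, SD, n = 2). The regions covered 12.8 Mb in replicate 1 and 15.5 Mb in replicate 2, with median widths of 933 bp and 1006 bp. A list made by the authors from both replicates together, called the pooled list here, held 55034 summits in 19950 regions. The confidence intervals below are 95% Wilson intervals over regions and cover counting error only. The labels give no treatment and no second group, so the comparisons are between replicates and between gene groups, region classes and sequence motifs within them.

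The first comparison was of the 2 replicates with each other. Most open regions of the embryonic intestine were found in both pools of embryos. Of the regions of replicate 1, 89.0% (88.5 to 89.5) were found in replicate 2, and of the regions of replicate 2, 77.7% (77.0 to 78.3) were found in replicate 1. Promoter regions were shared more often than distal regions, those with a summit more than 1000 bp from every annotated start. The shares were 95.2% of 10658 promoter regions and 66.9% of 2962 distal regions in replicate 1, and 86.2% of 11646 and 51.4% of 3776 in replicate 2. Promoters of Cdx2, the homeobox regulator of intestinal identity, of Cdh1, which encodes E-cadherin, and of Acta2, which encodes smooth muscle actin, were among those open in both. Regions with a strong signal were nearly always shared, with 99.5% and 99.1% shared in the strongest of 4 equal parts of each list. In the weakest part 76.3% of replicate 1 regions and 45.4% of replicate 2 regions were shared. Promoter regions also ranked higher by signal value than intron and intergenic regions. Promoter and distal regions were not compared at equal signal, so class and signal cannot be told apart here. Lists shifted along the chromosomes shared a mean of 0.743% and 0.655% of regions, and both shares had p = 0.001 in a one-sided permutation test, the smallest that 1000 shifts can give.

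**Figure D1:**
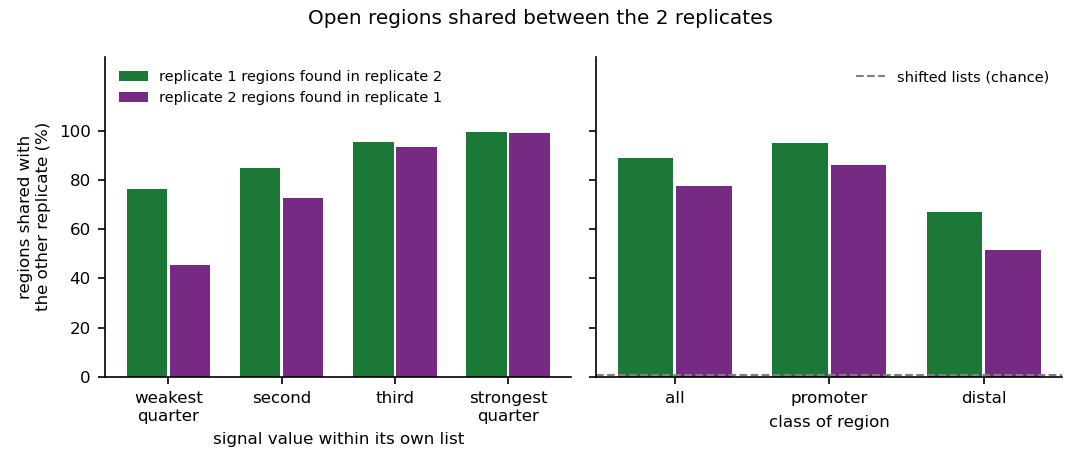
Percent of regions (vertical axis) of replicate 1 (green) and replicate 2 (purple) found in the other replicate, in 4 equal parts by signal value within the list (left) and by class of region (right), with the mean of shifted lists as a dashed line. Sharing was lowest in the weakest part, at 76.3% and 45.4%, and at distal regions, at 66.9% and 51.4%.

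Across 12126 shared regions, the ranks of the signal value in the 2 replicates had a Spearman correlation of 0.809. It was 0.811 across 10145 shared promoter regions and 0.673 across 1981 shared distal regions. These are correlations across regions, which are not independent replicates, so no p-value is given. With both lists limited to the 13620 regions ranked highest by signal value, 2178 regions (16%, 15.4 to 16.6) were found in replicate 1 alone and 2347 (17.2%, 16.6 to 17.9) in replicate 2 alone. Promoters made up 43.7% (41.6 to 45.8) and 45.6% (43.6 to 47.6) of these, against 84.8% and 85.0% of the shared regions. Among gene groups, regions of replicate 1 alone were nearest to gut mesenchyme genes 13 times and to smooth muscle and interstitial cell genes 11 times, against 5 and 4 times for replicate 2 alone. These were the widest gaps among the 23 lists, picked after the counts were seen. Forebrain genes, a contrast list, leaned the same way (6 against 1), and blood and immune cell genes (1 against 4) and housekeeping genes (4 against 7) leaned the other way. For intestinal epithelial transcription factors the number was 14 in each replicate. With 1 library on each side, no difference between the replicates was tested.

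The next comparison asked where open regions lie with respect to genes. Promoters dominated the lists of both replicates. The share of regions with their strongest summit within 1000 bp of an annotated transcription start was 76.9% ± 1.94 (SD, n = 2), and it was 65.6% (64.9 to 66.3) in the pooled list. Summits shifted along the chromosomes gave a mean of 6.39% in each replicate and 6.38% for the pooled list (one-sided permutation p = 0.001 in each, the smallest possible). Introns held 10.2% ± 0.750 and intergenic sequence 11.5% ± 1.07 of regions (SD, n = 2), against 38.2% and 52.6% of random positions. Promoter regions also ranked higher, with a median percentile of signal value of 63.6 in the pooled list against 28.7 for introns and 32.2 for intergenic regions. Of 21911 protein-coding genes, 10430 (47.6%) had an open promoter in both replicates and 12600 (57.5%) in the pooled list. An open promoter was found for 1.19% of genes in the lowest of 10 equal classes by CpG content of the promoter and 95.9% in the highest. In the less strict peak lists the promoter share fell to 45.8% over the replicates and 36.8% for the pooled list.

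Of 37 genes chosen before the data were examined, 15 had a promoter region in both replicates and in the pooled list. Epithelial genes among them were Cdx2 (chr5:147306707-147307807, pooled coordinates), Gata6 (chr18:11051973-11053393), Sox9 (chr11:112781690-112783136), Vil1 (chr1:74408399-74409530), which encodes a microvillus protein, Epcam (chr17:87635508-87637288), Cdh1 (chr8:106603125-106603906), Isx (chr8:74871750-74872805) and Lgr5 (chr10:115586850-115588051), a marker of intestinal stem cells. Hedgehog signalling genes were the ligand Ihh (chr1:74951187-74952279) and the receptor Ptch1 (chr13:63565918-63566723 in the pooled list, at another annotated start than in replicate 1). Mesenchymal and muscle genes were Foxf1 (chr8:121083386-121084717), Nkx2-3 (chr19:43611891-43612785), Acta2 (chr19:34255164-34255789) and Kit (chr5:75574491-75576231), a marker of interstitial cells of Cajal. Sox2 (chr3:34649217-34650644), a transcription factor of the stomach and other tissues, completed the 15. Over all protein-coding genes 47.6% had a promoter region in both replicates, so the count of 15 of 37 does not set the chosen genes apart. Coordinates are on mm10, and starts are those of GENCODE M21. Cdh1 and Nkx2-3 ranked highest of these, at percentiles 68.2 and 68.3 of signal value in the pooled list, and Ptch1 ranked lowest, at 4.0.

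No promoter region was found in the 3 thresholded lists for Cdx1, Shh, Neurog3, Fabp2, Barx1, Actg2, Phox2b, Sox10, Cdh5, Ptprc, Alb and Myod1, which mark the early epithelium, endocrine precursors, enterocytes, mesenchyme, smooth muscle, enteric neurons and glia, endothelium, blood, liver and skeletal muscle. Hnf4a was open in replicate 1 and the pooled list, Pdgfra and Ret in replicate 2 and the pooled list, and Atoh1 in replicate 2 alone. Gata4, Foxa2, Gli1, Myocd, Myh11 and Foxg1, a forebrain gene, had a promoter region in the pooled list alone. The thresholded lists hold only regions past a strict threshold. In the 3 less strict lists Actg2 had a promoter region in 3, Fabp2 and Barx1 in 2, and Cdx1, Phox2b and Sox10 in 1.

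Gene groups were then compared at promoters, with 23 lists fixed before the data were examined. In 4 of them fewer promoters were open than in random lists matched on CpG decile, in both replicates and in the pooled list. No list passed as having more open promoters, but even a list with all promoters open could fail to pass. Housekeeping genes had 24 of 24 open in the pooled list and in replicate 2, with adjusted p = 0.252 and 0.0547 by permutation. The test therefore cannot show that no list had more. Enteric neuron and glia genes had 7 of 25 promoters open in the pooled list (28.0%, against 66.3% ± 7.14, SD of random lists) and 2 and 4 in replicates 1 and 2 (ratios to random lists 0.142 and 0.263, against 0.422 pooled), with Chat and Ascl1 among those without a region in either replicate. Forebrain genes had 9 of 24 open (37.5% against 82.3% ± 6.57) and 5 in each replicate (ratios 0.29 and 0.271, against 0.456 pooled), without Dlx5 and Emx1. Genes of lung, kidney and skin had 1 of 20 open (5.0% against 39.4% ± 7.29), with 0 and 1 in the replicates, without Dsg3 and Krt1. Hox genes, which set position along the body axis, had 11 of 39 open (28.2% against 81.4% ± 5.46). In replicates 1 and 2, 3 and 10 were open (ratios 0.109 and 0.339, against 0.347 pooled). Hox genes lie in clusters of neighbours, whereas the random lists draw genes across the genome. Their SD and p thus treat the Hox promoters as independent. The open Hox promoters of the pooled list were Hoxa1, Hoxa4, Hoxa7, Hoxb2, Hoxb3, Hoxb4, Hoxc4, Hoxc5, Hoxc6, Hoxc10 and Hoxd1.

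The permutation test was two-sided with Benjamini-Hochberg adjustment over the 23 lists. All 4 lists had an adjusted permutation p = 0.00115 in replicate 1 and in the pooled list, which rests on 0.0002, the smallest that 10000 random lists can give. In replicate 2 the adjusted permutation p was 0.00153 for enteric neurons and glia, forebrain and Hox genes, and 0.0023 for lung, kidney and skin. In the less strict lists 3 of the 4 no longer passed. There the pooled ratio to random lists was 0.975 for enteric neurons and glia (adjusted p = 1.0 by permutation, 0.00115 to 1.0 over all alternatives), 0.685 for lung, kidney and skin (0.162, from 0.00115) and 0.867 for Hox genes (0.0745, from 0.00115). For Hox genes the random lists were 91.6% open in the less strict pooled list, against 81.4% in the thresholded one. A call lost in the less strict lists does not show that the difference ended. Forebrain genes lost their call against random lists not matched on CpG content (ratio 0.652, adjusted permutation p = 0.101, from 0.00115).

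In 2 lists of the intestinal epithelium more promoters were open in the pooled list, without passing in both replicates. Intestinal epithelial transcription factors had 24 of 28 promoters open (85.7% against 68.0% ± 6.40, adjusted p = 0.0238 by permutation), but the adjusted p was 0.974 and 0.698 in replicates 1 and 2. Epithelial structure genes had 21 of 32 open (65.6% against 46.9% ± 6.25, adjusted permutation p = 0.0238), with 0.974 in replicate 1 and 0.0353 in replicate 2, so that 1 list was higher without replicate 1. In the less strict lists 2 lists were higher, epithelial structure with a ratio of 1.58 and smooth muscle and interstitial cells of Cajal with 1.51. The thresholded pooled list held 16 of 24 promoters of that muscle list (66.7% against 50.1%).

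Other lists of the gut did not pass in all 3 lists. Absorptive enterocyte genes had 8 of 25 promoters open (32% against 30.8%), secretory and enteroendocrine genes 11 of 29 (37.9% against 51.1%) and stem cell and Wnt response genes 15 of 20 (75.0% against 81.3%). The absorptive list turned to a ratio of 0.557 against random lists not matched on CpG content. Gut mesenchyme genes had 25 of 37 open (67.6% against 71.1%), Hedgehog pathway genes 14 of 16 (87.5% against 84.4%), endothelial genes 8 of 22 (36.4% against 49.4%), blood and immune cell genes 5 of 25 (20% against 26.1%) and mesothelial genes 5 of 13 (38.5% against 48.5%). Proliferation genes had 22 of 23 open (95.7% against 89.0%) and housekeeping genes 24 of 24 (89% in random lists). The remaining contrast lists were liver with 1 of 19 open (5.26% against 17.4%), pancreas with 2 of 16 (12.5% against 37.0%, adjusted p = 0.0309 by permutation in the pooled list alone), stomach with 3 of 16 (18.8% against 31.0%), heart with 5 of 16 (31.2% against 39.8%), skeletal muscle with 4 of 16 (25% against 37.2%) and photoreceptor and olfactory genes with 3 of 18 (16.7% against 30.3%). For 7 of these lists the ratio to random lists in a replicate lay on the other side of 1 from the pooled ratio or over 1.5 times from it. Absorptive enterocyte genes had a ratio of 0.667 in replicate 1 and 0.75 in replicate 2 (1.04 pooled), and Hedgehog pathway genes 0.771 and 0.796 (1.04 pooled), so both lists turned below random with either replicate left out. The ratios were 0.368 and 0.511 for mesothelial genes (0.792 pooled), 0.441 and 0.764 for liver (0.303), 0.978 and 0.669 for stomach (0.605), 0.399 and 0.36 for heart (0.784) and 0.237 and 0.64 for photoreceptor and olfactory genes (0.55). Gut mesenchyme and mesothelial genes were lower in replicate 1 (both adjusted p = 0.0284 by permutation) and endothelial genes in replicate 2 (0.0313), so that 5 lists were lower without replicate 1 and 6 without replicate 2. In the top-ranked 50% of regions gut mesenchyme genes (ratio 0.416, highest adjusted permutation p = 0.011) and endothelial genes (ratio 0, 0.0046) were also lower in all 3 lists. Against random lists not matched on CpG content, absorptive enterocyte, blood and immune cell, liver, pancreas, skeletal muscle, and photoreceptor and olfactory genes were also lower, and proliferation (1.67) and housekeeping genes (1.74) were higher.

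**Figure D2:**
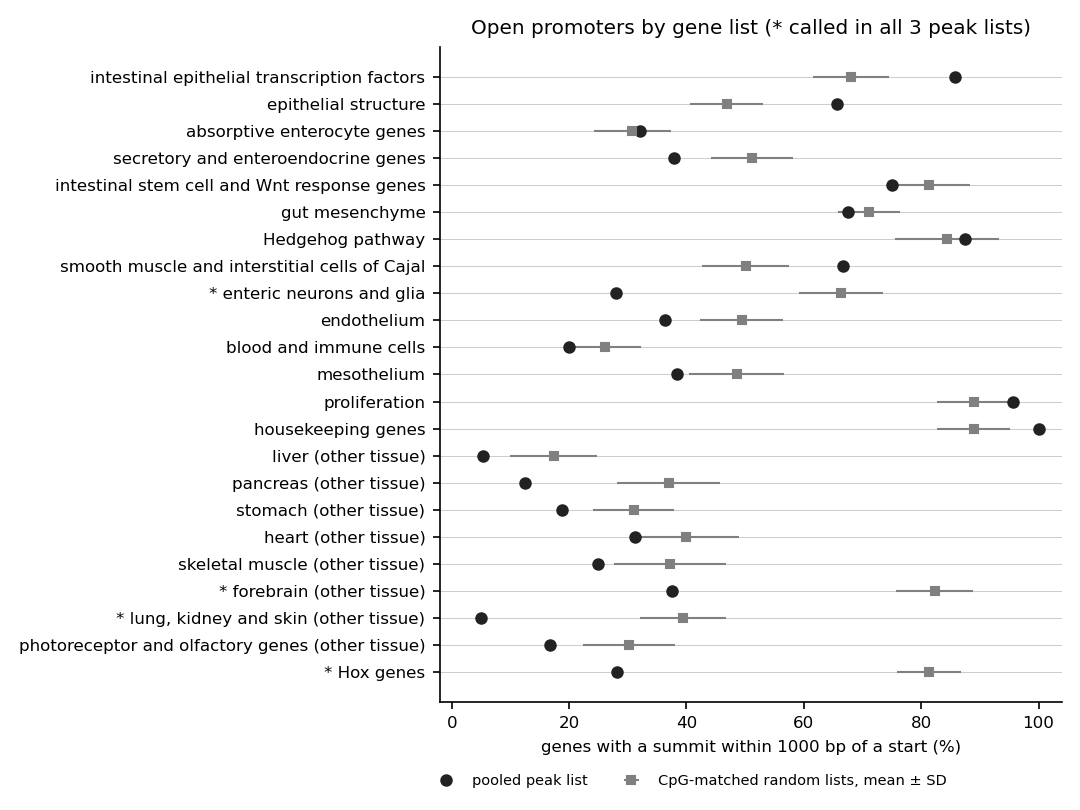
Percent of each gene list's members with an open promoter in the pooled list (black, horizontal axis) and in CpG-matched random lists (grey, mean ± SD); an asterisk marks the lists that passed in all 3 peak lists. The Hox list sits at 28.2% against 81.4%, and the forebrain list at 37.5% against 82.3%.

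Gene groups were also compared by the distal regions nearest to them. Intestinal epithelial transcription factors had 58 distal regions in the pooled list, 3.90 times the mean of random lists matched on the decile of territory length. Of the 28 genes, 21 had at least 1. The ratio was 3.74 in replicate 1 and 4.09 in replicate 2. Sox9, a regulator of epithelial progenitors, had most, with 8 regions in the pooled list and 4 and 5 in the replicates. Klf4, a zinc finger regulator of epithelial differentiation, and Tcf7l2, an effector of Wnt signalling, had 5 each. Hedgehog pathway genes had 24 distal regions, 2.86 times the random mean, with ratios of 3.58 and 3.08 in the replicates. Gas1, a Hedgehog co-receptor, had 6, Gli2, a transcription factor of the pathway, had 3 and Boc, another co-receptor, had 2.

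The permutation test was two-sided and adjusted over 23 lists. For epithelial transcription factors the adjusted p was 0.0092 in replicate 1, 0.0023 in replicate 2 and 0.0046 in the pooled list. For the Hedgehog pathway these permutation values were 0.0345, 0.0353 and 0.0195. No list passed as having fewer distal regions, but even a count of 0 could fail to pass. Photoreceptor and olfactory genes had 0 distal regions in both replicates, with adjusted p = 0.657 and 0.66 by permutation. The test therefore does not show that no list had fewer. The Hedgehog call ended with promoter windows of 500 bp (ratio 2.85, adjusted p = 0.0598 by permutation) or 2000 bp (2.73, 0.101), within 50 kb of the start (2.63, 0.727), in the top-ranked 50% of regions (3.01, 0.55), and when random lists were also matched on an open promoter (2.51, 0.0713). Its adjusted p ranged from 0.00307 to 0.727 over all alternatives. The call for epithelial transcription factors ended in the top-ranked 50% alone (ratio 1.97, adjusted p = 0.837 by permutation, range 0.0023 to 0.837).

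The distal region nearest to Sox9 with the highest signal value in the pooled list and in replicate 2 lay at chr11:113147491-113148488, 366 kb downstream in an intron of 2610035D17Rik, and was found in both replicates. In replicate 1 a region at chr11:112010940-112011165, 771 kb upstream, ranked higher. The closest lay at chr11:112784341-112785347 in an intron of Sox9 and was also found in both. A region at chr11:113052244-113053388 was the remaining one found in both replicates. For Gas1, regions at chr13:60109979-60110899 and chr13:60307986-60309054 were found in both replicates. For Klf4 these were chr4:55514581-55515394 and chr4:55650873-55651805. Assignment to the nearest start does not show which gene a region acts on.

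**Figure D3:**
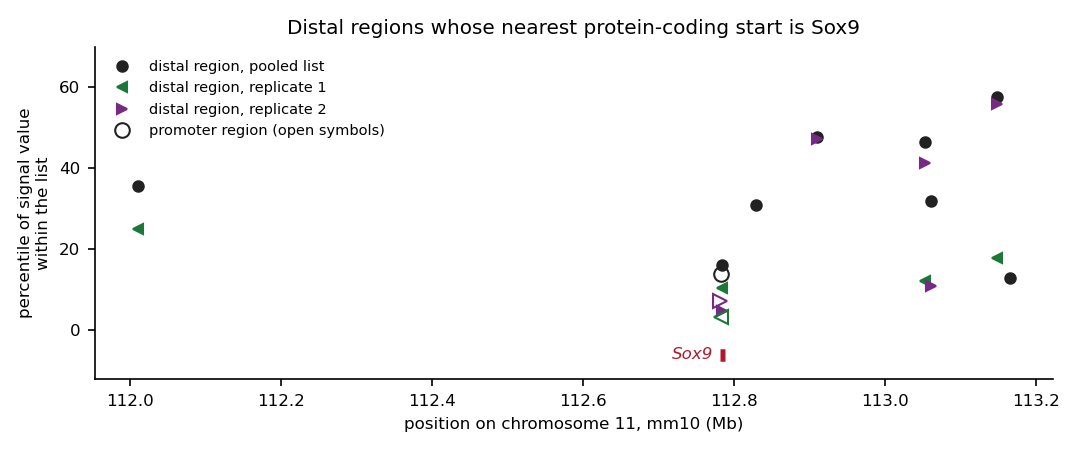
Percentile of signal value within each list (vertical axis) of the distal regions nearest to Sox9 (filled) and of its promoter region (open) along chromosome 11 in Mb (horizontal axis), for replicate 1 (green), replicate 2 (purple) and the pooled list (black). The distal region ranked highest in the pooled list, at percentile 57.7, lies 366 kb downstream.

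For 4 other gene lists the permutation test passed in some of the peak lists. Epithelial structure genes had 20 distal regions (ratio 2.85, adjusted p = 0.0138 by permutation pooled, 0.0889 in replicate 1 and 0.0023 in replicate 2), 3 of them nearest to Epcam. Stem cell and Wnt response genes had 33 (ratio 2.70, adjusted p = 0.0138 by permutation pooled, 0.14 and 0.0333 in the replicates), 5 of them nearest to Rnf43, a feedback inhibitor of Wnt signalling. Proliferation genes had 13 (ratio 2.41, with 2.17 and 3.66 in the replicates) and housekeeping genes 13 (ratio 2.55), and each passed in replicate 2 alone. Thus 6 lists had more distal regions without replicate 1, and 2 without replicate 2. Gut mesenchyme genes had 32 (ratio 1.3), 5 of them nearest to Meis1, and passed in the less strict lists, where the ratio was 1.81 and 5 lists passed. Smooth muscle and interstitial cell genes had 16 (ratio 1.81), absorptive enterocyte genes 12 (1.29), secretory and enteroendocrine genes 8 (0.817), enteric neuron and glia genes 11 (0.98), endothelial genes 9 (0.997), blood and immune cell genes 9 (1.48) and mesothelial genes 6 (1.05). The 8 contrast lists of other tissues ranged from a ratio of 0.2 for photoreceptor and olfactory genes to 2.03 for lung, kidney and skin, and Hox genes had 6 regions (1.63). From smooth muscle on, none of these lists passed in any of the 3 thresholded lists. Several of these ratios rested on few regions and turned or moved by over 1.5 times with 1 replicate left out. In replicates 1 and 2 they were 2.64 and 1.04 for smooth muscle and interstitial cells, 0.471 and 0.371 for secretory and enteroendocrine, 0.843 and 0.501 for enteric neuron and glia, 1.32 and 1.03 for endothelial and 0 and 0.324 for mesothelial genes. Hox genes had 1 region in replicate 1 (0.639) and 0 in replicate 2. Among contrast lists they were 0 and 0.291 for pancreas (0.63 pooled), 0.437 and 1.03 for stomach (1.13), 0.496 and 0.773 for skeletal muscle (0.86), 0.569 and 0.606 for forebrain (0.973) and 0 in both for photoreceptor and olfactory genes. In simulated data with the pooled list alone, 52.5% of lists with 3 times as many distal regions passed and 27.5% with 2 times as many. A call here also needed both replicates, which hold fewer distal regions. A list that did not pass may therefore still differ.

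**Figure D4:**
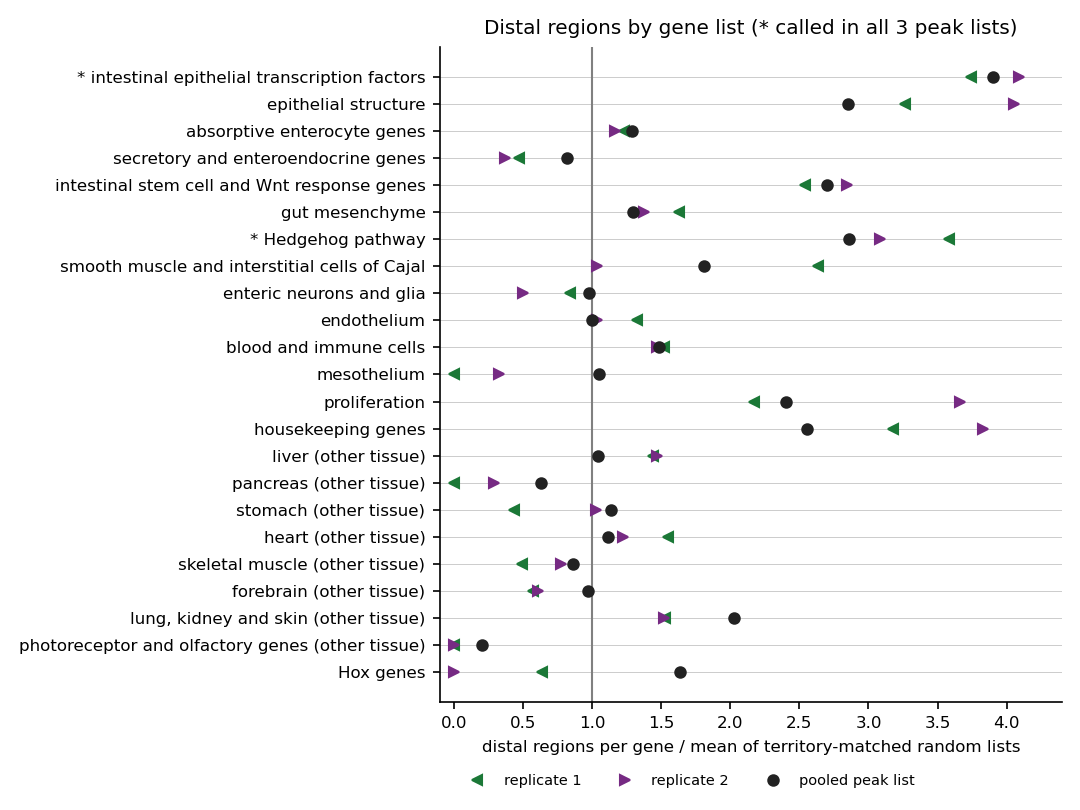
Distal regions per gene divided by the mean of territory-matched random lists (horizontal axis) for each gene list in replicate 1 (green), replicate 2 (purple) and the pooled list (black); an asterisk marks the lists that passed in all 3 peak lists. Epithelial transcription factors lie at 3.74, 4.09 and 3.90.

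Transcription factor motifs were compared between distal summits and the flanks of the same regions. Of 38 motifs, 3 of them scrambled controls, 12 were more frequent within 100 bp of distal summits in both replicates and in the pooled list. The CTCF motif, bound by the factor that holds chromatin loops, was found at 440 of 6861 distal summits (6.41%, 5.86 to 7.02) against 0.226% of flanking windows, a ratio of 28.4. Among motifs of intestinal epithelial factors, the extended CDX motif was at 6.43% of summits (ratio 2.53), HNF4 at 1.53% (6.36), the longer HNF4 repeat at 0.889% (5.08) and GATA at 5.90% (2.27). The ratios in replicates 1 and 2 were 2.03 and 2.70 for the extended CDX motif, 6.92 and 9.07 for HNF4, and 2.06 and 2.88 for GATA. The extended CDX motif is the motif of CDX and posterior HOX factors with 1 more base. That shorter motif was not called, with a ratio of 1.03 in the pooled list and 0.820 and 1.08 in replicates 1 and 2. KLF and SP motifs were at 4.33% (ratio 5.35), AP-1 at 10.1% (2.71), TEAD at 6.25% (2.06), the CAGCTG E-box of basic helix-loop-helix factors at 19.6% (2.02) and NFY at 4.71% (2.47). The rarest were ELF and ETS at 15 summits (ratio 6.0) and NRF1 at 17 (6.8). In replicates 1 and 2 the ratio was 3.14 and 4.20 for the longer HNF4 repeat and 3.94 and 2.91 for NFY. ELF and ETS were at 10 and 13 summits against 2 and 3 flanking windows, and NRF1 was at 11 and 14 summits against 0 and 2.

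The binomial tests were exact, two-sided and adjusted over 38 motifs. The adjusted p in the pooled list was 1.42e-107 for CTCF, 1.58e-25 for the extended CDX motif, 5.3e-14 for HNF4, 1.34e-17 for GATA and 0.0319 for ELF and ETS. NRF1 had no flanking match in replicate 1, where the motif was at least 7.33-fold more frequent at summits, with 3 windows over both flanks as the floor. That floor was chosen after the first motif results were seen, and without it NRF1 did not pass and 11 motifs did. The TAATTA homeobox motif was less frequent at summits (2.67%, ratio 0.533), and so were 2 of the 3 scrambled control motifs, those made from GATA (0.687) and FOX (0.654). The flanks were thus not a neutral background. A difference in base composition is a possible reason, but composition was not measured. Against shuffled windows of equal dinucleotide content the same 12 motifs passed, and no motif passed as less frequent. Their pooled ratios there were 44 for CTCF, 6.21 for the extended CDX motif, 10.2 for the longer HNF4 repeat, 11 for KLF and SP, 3.75 for ELF and ETS, 1.5 for NFY and 1.33 for CAGCTG. TAATTA turned to more frequent there and passed in all 3 lists (ratio 1.91, highest exact adjusted p = 0.0248). The scrambled GATA control turned to 1.80 and passed in the pooled list and replicate 2 (exact adjusted p = 4.94e-09 and 6.59e-05). In replicate 1 it did not pass (exact adjusted p = 0.162). Its pooled ratio lay above those of NFY and CAGCTG and near that of TAATTA. Shuffled windows alone thus do not set these motifs apart from a control. There the motif of CDX and posterior HOX factors also passed, with a ratio of 2.99 against 1.03 with flanks.

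HNF1, FOX, GRHL and SOX motifs passed in the pooled list and replicate 2 and not in replicate 1. HNF1 was at 26 summits and 1 of the flanking windows in the pooled list. FOX was at 308 summits (4.49%, ratio 1.63, exact adjusted p = 2.39e-07), GRHL at 23 (ratio 7.67, exact adjusted p = 0.00204) and SOX at 339 (4.94%, ratio 1.33, exact adjusted p = 0.00204). CAGCTGTT, planned as a double E-box motif, holds only 1 E-box, the CAGCTG counted above. It passed in the pooled list and replicate 1 (ratios 2.33 and 2.19, exact adjusted p = 5.32e-06 and 0.0115). NFI, at 9 summits and no flanking window, passed in the pooled list alone (exact adjusted p = 0.00781). The CATCTG E-box was less frequent in replicate 2 alone (ratio 0.807, exact adjusted p = 0.0011). The scrambled CTCF control had a ratio of 3.60 in the pooled list (exact adjusted p = 0.0251) and did not pass in either replicate. It passed in the less strict lists, where ELF and ETS did not. In the top-ranked 50% of regions 5 of the 12 motifs passed, and the extended CDX, HNF4, longer HNF4, GATA, ELF and ETS, TEAD and NRF1 motifs did not.

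**Figure D5:**
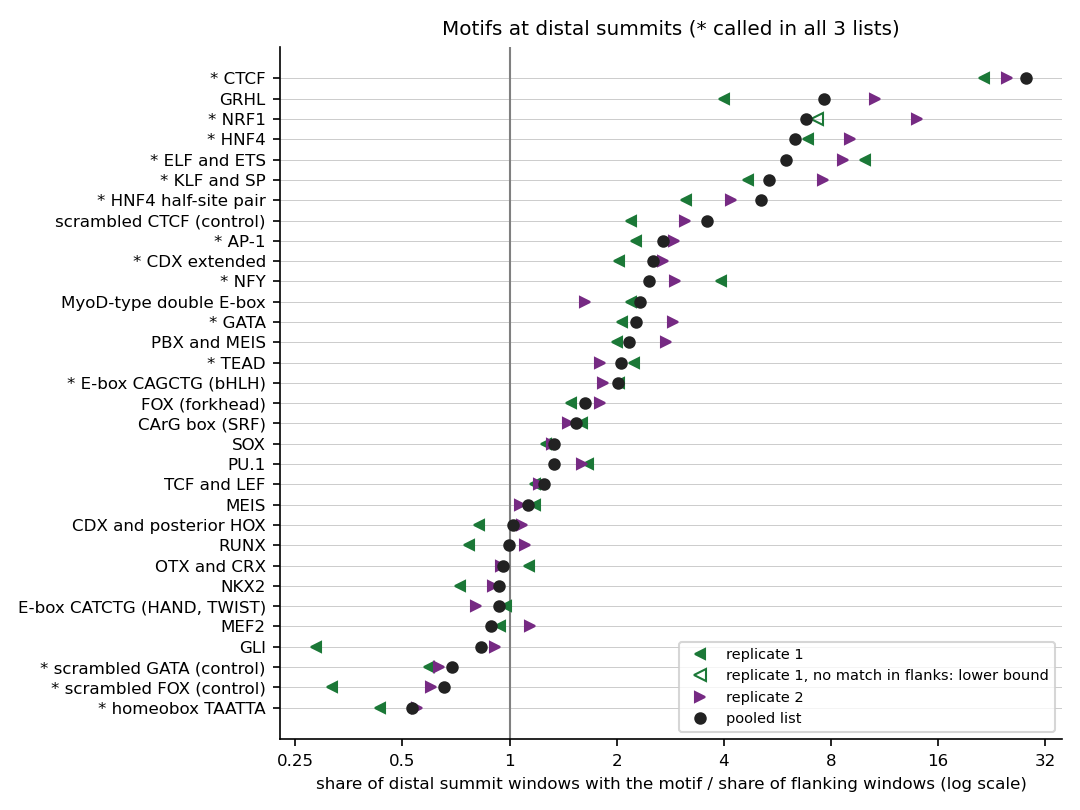
Share of distal summit windows with each motif divided by the share of flanking windows (horizontal axis, log scale) in replicate 1 (green), replicate 2 (purple) and the pooled list (black); asterisks mark motifs that passed in all 3 lists, and motifs with fewer than 10 summits or at most 3 flanking matches in the pooled list, HNF1 among them, are not drawn. Of the motifs drawn, CTCF lies highest, with a ratio of 28.4 in the pooled list.

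Of the 10 regions ranked highest in both replicates, 7 were intergenic, 2 lay in introns of other transcripts and 1 at a start of Gm11407. Their distance to the nearest protein-coding start ranged from 11202 bp (Hic2) to 1765843 bp (G6pd2), with 12238 bp for Myl12b and 12987 bp for Abcb11. The strongest, chrX:143482937-143483180 in replicate 1 coordinates, lay 35531 bp from Pak3, with the highest signal value of each list. The next were chr2:69355471-69355735 near Abcb11, chr10:96077547-96077951 near Gm5426 and chr5:60042765-60043140, 1765843 bp from G6pd2. The others lay at chr2:3964430-3964690 near Frmd4a, chr12:97061368-97061856, 1154982 bp from Galc, chr17:70963583-70963961 near Myl12b, chr16:17222207-17222580 near Hic2, chr4:80002706-80003054, 831189 bp from Tyrp1, and chr9:3258742-3259179 near Alkbh8. Their median width was 375 bp, against 647 bp for the other distal regions of replicate 1. Of the 10, 5 held a match to mitochondrial DNA.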

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

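The test of the Hox list against unmatched random lists was planned before the data were examined, but it was turned to this question only after its result had been seen. The tests of mitochondrial and nuclear copies and of the less strict list were written down before their results were seen.

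In replicate 1, 160 summits, and in replicate 2, 179 summits passed an IDR of 0.05 in the ranked lists and were absent from the thresholded lists, a signal in data that no comparison used. Of these, 30 and 40 lay on unplaced scaffolds. The others lay in 55 and 61 chromosomal regions, of which 1 in each replicate matched mitochondrial DNA (chr1:24611587-24616168 in replicate 1, with 14 summits, and chr1:24611586-24616156 in replicate 2, with 16, at 99.956% identity).

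The 10 regions ranked highest in both replicates were mostly intergenic, and all lay 11202 to 1765843 bp from the nearest protein-coding start. Copies of mitochondrial DNA in the nuclear genome are a candidate explanation for part of the 10. Such a match was held by 5 of the 10, those near Abcb11, Gm5426, G6pd2, Galc and Tyrp1, against 2 of 2953 other distal regions (0.0677%). A copy elsewhere in the nuclear genome was found for 2 of the 10, near G6pd2 and Tyrp1, and for 4 of 200 other distal regions (2.0%). That count lies between the values that would have argued for and against repeated nuclear sequence, and both regions also matched mitochondrial DNA, so the 2 explanations cannot be told apart for them. The 5 regions near Pak3, Frmd4a, Myl12b, Hic2 and Alkbh8 had neither kind of match and stay open, and no biological explanation was tested.

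Hox promoters were open less often than promoters matched on CpG decile, at 11 of 39 against 81.4% ± 5.46 in random lists. The matching on CpG content did not account for it, because the unmatched share was 57.4% ± 7.84 (adjusted p = 0.00153 by permutation). The strict threshold remains a candidate explanation. In the less strict pooled list 31 of 39 were open, 79.5% against 91.6% ± 3.96 (adjusted p = 0.0745 by permutation), and the ratio to random lists rose from 0.347 to 0.867. Most Hox promoters reached that list and the call ended there, which does not show that no difference was left. Most CpG-matched promoters also reached it, which by itself brings the ratio nearer to 1. The lost call therefore cannot decide whether the threshold accounts for the difference. The random lists do not follow the clustering of Hox genes, and no biological explanation was tested.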

How the results depend on the processing

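Of the alternatives in this part, those chosen only after seeing results were the tests with ranks by −log10 p, every summit counted, random lists matched also on an open promoter, and no call for motifs without a flanking match. Every alternative planned beforehand was run. Replicate overlap and promoter share kept their direction and their p in every alternative run, with 74.4% to 89.1% and 70.4% to 82.8% of regions shared and 45.8% to 89.9% at promoters. No list passed as having fewer distal regions in any alternative run, a test that lists with 0 regions could fail. In the less strict lists the rank correlation was 0.797, 2 gene lists were higher and 1 lower at promoters, and 5 were higher at distal regions. In the top-ranked 50% these were 0.637 for the rank correlation, 0 lists at distal regions, 5 motifs higher and 0 lower, with fewer regions tested; gut mesenchyme (0.416) and endothelium (0) became lower at promoters. Ranked by −log10 p, the rank correlation was 0.846, replicate-only regions made up 14.0% and 15.2%, and 36.3% and 54.1% of these were at promoters. At their own length the lists had 11% and 22.3% of regions in 1 replicate only, 34.3% at promoters in replicate 1. Without matching, 2 lists were higher and 9 lower at promoters and 4 higher at distal regions, and absorptive enterocyte genes turned to a ratio of 0.557. Lists with more distal regions numbered 1 with each of promoter windows of 500 and 2000 bp, a limit of 50 kb and matching on an open promoter. With 1 replicate left out, lists higher at promoters numbered 0 to 1 and lists higher at distal regions 2 to 6, since fewer lists had to pass. Against shuffled windows 0 motifs were lower, the scrambled GATA control turned to 1.80 and did not pass in replicate 1, TAATTA turned from lower to higher and passed (1.91), and CDX and posterior HOX (2.99), FOX (3.31), SOX (1.81) and PBX and MEIS (4.33) passed. Except where stated, the cause was not tested. No paired analysis was possible because there is 1 group. Depth is unknown, so whether it differed between the replicates cannot be stated.

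Single motifs changed their call as follows, with the ratio under each alternative. In the less strict lists HNF1 (12.8), FOX (1.71), GRHL (3.94), NFI (15.4), CAGCTGTT (2.47) and the scrambled CTCF control (2.16) passed as higher. The PHOX2 pair (0.389) passed there as lower, and ELF and ETS (1.90) no longer passed. In the top-ranked 50% the extended CDX (2.61), HNF4 (16), longer HNF4 (3.25), GATA (2.45), ELF and ETS (4.0), TEAD (1.90), NRF1 (14), TAATTA (0.434), scrambled GATA (0.515) and scrambled FOX (0.466) motifs no longer passed. With windows of 50 bp the longer HNF4 (4.14), ELF and ETS (7.0) and NRF1 (20) motifs were lost. With 200 bp ELF and ETS (2.38) and scrambled GATA (0.879) were lost, and FOX (1.43), SOX (1.27) and NFI (30) passed. ELF and ETS (4.0) were lost with the conservative pooled list, scrambled FOX (0.820) with shuffled windows, and NRF1 (6.8) without the floor. With 1 replicate left out the ratio was 0.820 to 1.08 for CDX and posterior HOX, which turned lower without replicate 2. It was 12 to 32 for HNF1, 1.49 to 1.80 for FOX, 4.0 to 10.7 for GRHL and 1.27 to 1.32 for SOX. For the CATCTG E-box it was 0.807 to 0.980, and for CAGCTGTT 1.63 to 2.19. Ratios of HNF1, GRHL, NFI, NRF1 and ELF and ETS rest on few flanking matches.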

Other observations

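The comparison of motifs in the thresholded list had no prediction of its own, and the search of the other replicate's less strict list was chosen only after the unshared regions had been seen; the 2 motif tests in the less strict list were written down before their results were seen. In the pooled lists, distal regions nearest to genes of different gut layers differed in their motifs. The lists of the single replicates were not tested for this, unlike for the calls above. Epithelial genes here were the lists of epithelial transcription factors, epithelial structure, absorptive enterocytes, and stem cells and Wnt response. The secretory and enteroendocrine list was left out. Of 456 distal regions of the less strict pooled list nearest to epithelial genes, 77 (16.9%) held a CDX, HNF4, HNF1 or GATA motif, against 37 of 306 (12.1%) nearest to mesenchyme and smooth muscle genes (one-sided permutation of gene labels, p = 0.0497, and 0.0497 after adjustment over both motif sets). A TEAD, CArG or CAGCTG motif was held by 92 of the 306 (30.1%) nearest to mesenchyme and smooth muscle genes and by 95 of the 456 (20.8%) nearest to epithelial genes (p = 0.0068 by permutation, adjusted 0.0136). In the thresholded pooled list the shares were 27.0% of 115 against 14.6% of 48 for the first set (p = 0.0382 by permutation, adjusted 0.0382). For the second set 35.4% near mesenchyme and smooth muscle genes stood against 21.7% (permutation p = 0.0355, adjusted 0.0382). The mesenchyme and smooth muscle side rested on 7 and 17 of the 48 regions. Both pooled lists come from the same alignments, so the second comparison is not separate support. Over all distal regions of the less strict pooled list the shares were 11.4% for the first set and 25.8% for the second, so the gap of the second set combines a higher share near mesenchyme and smooth muscle genes with a lower share near epithelial genes. These values are consistent with the hypothesis that open regions of the epithelium and of the mesenchyme lie near genes of their own layer. The first difference lies close to the threshold. Measuring the layers apart would test the hypothesis itself, and that was not done.

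The less strict pooled list held 9 of 11 Hoxa, 8 of 10 Hoxb, 6 of 9 Hoxc and 8 of 9 Hoxd promoters. In the thresholded pooled list these were 3, 3, 4 and 1.

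Regions found in 1 replicate only were mostly present below the threshold in the other. Of 1494 regions of replicate 1 without a partner in the thresholded list of replicate 2, 1350 (90.4%, 88.8 to 91.8) overlapped a region of its less strict list. For replicate 2 these were 3094 of 3445 (89.8%, 88.8 to 90.8).

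Regions that matched mitochondrial DNA numbered 13 of 13620 in replicate 1 and 12 of 15422 in replicate 2, and 7 in each lay among the 50 regions with the highest signal value.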
